A study of Homo sapiens with 4 samples.

How the data were processed

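Ribosome profiling sequences the stretches of messenger RNA that translating ribosomes protect from nuclease digestion, so that the number of fragments (footprints) of a gene reflects both how much of its RNA is present and how densely it is loaded with ribosomes. The series held 4 libraries, 2 labelled wild type and 2 labelled METTL21B knockout, with replicate numbers 1 and 2 in each group. Per the labels' protocols, cells grown with fetal bovine serum were given cycloheximide briefly to stop elongating ribosomes and lysed with detergent. RNase I then digested the lysates, monosomes were collected from sucrose gradients, and the protected fragments were ligated to a linker, reverse transcribed, circularized and amplified. No library of total RNA was analysed here, so a change in footprints is not split into a change in RNA level and a change in translation.

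The sources name the cells differently. The sample labels give Flp-In T-REx-293, a derivative of the human embryonic kidney line HEK293, whereas the series design text describes haploid cells of human origin. Which of these is right was not settled, and the labels do not say whether the libraries of a group came from separate cultures or how many knockout clones were used. P-values of single genes therefore measure the spread between these libraries alone, which may be technical.

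The deposited table held whole-number read counts per gene for each of the 4 libraries, with a UCSC transcript identifier, a gene symbol and a RefSeq identifier on each row. CASAVA and Bowtie are named in the submitters' processing notes without versions, together with the build hg19, while the file header names the hg38 known gene table. Because of that disagreement no coordinates are given. The counting tool, its treatment of strand and of reads that match several places, the read lengths kept and any removal of ribosomal RNA reads are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of genes with near-identical copies (ribosomal proteins, EEF1A1, actins, tubulins, heat shock proteins) can be split or lost in ways that the table does not show.

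The table had 16464 rows, of which 2854 had 0 counts in all libraries. A missing symbol affected 1417 rows, which held 4.71% of all counts. These rows carry a transcript identifier, so they were kept in library sizes and tests, and 416 of them passed the filter. Spreadsheet software had turned 24 symbols into date numbers, and these were replaced by the symbol paired with the row's RefSeq accession. Symbols that occurred on more than 1 row were told apart by the transcript identifier. Older symbols were kept as the table gives them.

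Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the default filterByExpr rule (minimum count 10, minimum total count 15), which left 9633 genes with 99.4% of all counts. Library sizes were scaled by TMM, with factors of 1.01, 1.01, 0.989 and 0.987. The comparison of knockout with wild type used glmQLFit and glmQLFTest without covariates, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Log2 fold changes are knockout over wild type. Mean and SD of CPM (counts scaled to a common library total after TMM) are over 2 libraries per group. Where a group had 0 counts, a lower bound of the fold was computed against 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with a 95% exact binomial (Clopper-Pearson) interval. Bounds and intervals cover counting error only, since molecular identifiers are not described.

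Gene lists, 37 in all with 1353 entries, were fixed before the data were examined, as were the test and the rule for naming genes. Lists with at least 3 measured members (34 lists) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with its preset correlation of 0.01 between genes, and adjusted over the lists. Camera was also run with a correlation estimated from the data, and fry in its place. With an estimated correlation camera takes its degrees of freedom from the 4 libraries and not from the genes, which leaves it little power. Camera compares a list with the other genes, whereas fry was used to test whether its members shifted in a common direction against no change. A list can thus pass fry in a comparison where many genes change without standing apart from them. A list whose members changed in both directions need not pass. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. Genes were named by the following rule. METTL21B, EEF1A1 and EEF1A2 were named first. The 8 largest rises and 8 largest falls followed, among genes past the threshold with a mean of at least 10 CPM and with both knockout libraries on the same side of both wild-type libraries. The 5 risen and 5 fallen genes with the highest mean CPM were added, and up to 4 members with the lowest p of each list that passed its test or had members past the threshold. Not every gene picked by this rule is described in the text, and other members named there were chosen after their values were seen.

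The procedure was tested on simulated counts drawn from the means, library sizes and fitted dispersion of this comparison, with 9523 genes tested and 200 genes changed. That dispersion is a biological coefficient of variation of 0.0171. Of 50 genes changed at each fold size, 26% were recovered at 1.25 fold, 46% at 1.5 fold, 84% at 2 fold and 90% at 4 fold. Far fewer genes changed there than the 50.5% called in the data, which makes the adjusted threshold stricter. These shares therefore do not give the recovery in this comparison. Of 9301 unchanged genes 7 were called. That count holds only for a spread as small as the fitted one, so it does not give the false calls if the libraries of a group are not independent. With camera's preset correlation, a simulated list of 30 genes raised 1.5 fold had an adjusted p of 4.56e-25, and 0 of 35 unchanged lists were called. With an estimated correlation the raised list had a camera adjusted p of 0.279. Nearly all other genes were unchanged there, so these results do not show how camera behaves where many genes change.

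The fit was repeated with DESeq2 size factors, upper quartile scaling and library size alone in place of TMM, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter and a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, and counts thinned to the smallest library total. Chosen after the data were seen were a fit without rows that lack a symbol, edgeR likelihood ratio tests with an assumed biological coefficient of variation of 0.1 or 0.2, edgeR's glmTreat test against a fold of 1.5, and a fit without 2 blocks of neighbouring genes. The order of genes along chromosomes came from a RefSeq gene table on GRCh38.p14, used for names and neighbours alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.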

Results

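Footprints were counted in 4 libraries, 2 of wild-type cells and 2 of cells labelled as METTL21B knockouts. METTL21B, also called EEF1AKMT3, is a methyltransferase that modifies a lysine of the translation elongation factor eEF1A, which carries aminoacyl-tRNAs to the ribosome. The comparison asks which genes carry more or fewer translating ribosomes when this enzyme is missing. Sample labels name the kidney-derived line Flp-In T-REx-293, while the series design text speaks of haploid cells. Total counts were 2477081 and 2105744 in the wild-type libraries and 1528013 and 1572575 in the knockout libraries, and between 12119 and 12620 rows had counts in a library. Libraries of a group lay close together, with a chi-square per degree of freedom of 1.04 for the wild-type pair (p = 0.0018 over 9755 genes, chi-square test of counts, not a test between groups) and 1.15 for the knockout pair (p = 2.79e-21 over 9022 genes, same test). Pairs across the groups had values from 15.3 to 16.0. Both pairs thus differed by slightly more than sampling noise, and each library was counted as 1 replicate.

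METTL21B itself was read too rarely to check the labels. Its row held 3 and 5 counts in the wild-type libraries and 3 and 1 in the knockout libraries, below the count filter. The ratio of knockout to wild type was 0.757 with a 95% exact binomial interval from 0.167 to 2.83, and edgeR without the filter gave a log2 fold change of -0.39 (SE 0.99, adjusted p = 0.789). A frameshift or a deletion outside the counted part would also leave footprint counts in place, and the kind of lesion is not given in the sources used here. All directions below therefore rest on the libraries being what their labels say.

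The substrate of the enzyme was read deeply. EEF1A1, the form of eEF1A made in most cells, rose from 1614 ± 8.50 to 2145 ± 10.3 CPM (SD, n = 2 per group), a log2 fold change of 0.41 (SE 0.032, edgeR adjusted p = 8.48e-14). EEF1A2, the form typical of neurons and muscle, fell from 956 ± 42.6 to 848 ± 30.9 CPM, a log2 fold change of -0.17 (edgeR adjusted p = 8.03e-04), and this call was lost without wild-type replicate 1 (-0.13, edgeR adjusted p = 0.0711). In a likelihood ratio test with an assumed coefficient of variation of 0.2, EEF1A1 was not called (adjusted p = 0.369). EEF1A2 was not called with a coefficient of 0.1 or 0.2. EEF1A1 has many processed pseudogenes and resembles EEF1A2 closely, so their counts are uncertain if reads were shared. Beside each list count, the count from a likelihood ratio test at an assumed coefficient of variation of 0.2 is given as the count with the wider spread, higher genes first. Among 4 measured genes listed as methyltransferases of eEF1A lysines, METTL13 rose (log2 fold change 1.02), while METTL10 (-0.29), ECE2 (-0.23) and N6AMT2 (0.20) did not pass the test; the list as a whole did not pass either (limma camera adjusted p = 0.775), and the count adjusted over the list alone and that with the wider spread were also 1. The row named ECE2 carries a readthrough transcript that joins the methyltransferase gene EEF1AKMT4 to the peptidase gene ECE2, so its value is not that of the methyltransferase alone. None of 7 measured related protein methyltransferases passed with edgeR, over all genes, adjusted over the list alone or with the wider spread (list adjusted p = 0.317). Of 6 measured genes next to METTL21B, TSFM rose (0.49) and OS9 (-1.17) and CDK4 (-0.38) fell. Counts were the same adjusted over the list alone (0 and 1 with the wider spread, camera list adjusted p = 0.895). The call of CDK4 was lost without knockout replicate 2 (-0.16). With DESeq2 neither TSFM (0.48, adjusted p = 0.0821) nor CDK4 (-0.38, adjusted p = 0.069) was called.

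Elongation and termination factors moved in both directions. Of 13 measured, 5 rose and 4 fell, also when adjusted over the list alone (0 and 0 with the wider spread; list adjusted p = 0.884). EEF2, the translocase of the ribosome, rose by a log2 fold change of 0.40 and EEF1G by 0.27. Initiation factors were as mixed, with 15 of 40 measured members up and 14 down (15 and 15 adjusted over the list alone, 1 and 2 with the wider spread; list adjusted p = 0.968 with limma camera and 0.0429 with limma fry). The helicase EIF4A2 rose by 1.21 and EIF3E by 0.78. EIF1, which takes part in start codon choice (-0.67), and EIF4EBP1, an inhibitor of the cap-binding factor eIF4E (-2.20), fell. EIF4EBP1 lies in a run of 115 neighbouring genes whose median log2 fold change was -0.83.

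Across the genome, footprints differed between the groups for a large part of the genes. Of 9633 genes tested, edgeR called 2409 higher and 2451 lower in the knockout libraries (adjusted p under 0.05), which is 50.5% of the genes. DESeq2 called fewer of the same genes, 1286 higher and 1393 lower. In 4853 of the 4860 genes called with edgeR the groups did not overlap. Over all tested genes the share without overlap was 74.5%, against 33.3% by chance with 2 libraries each. Folds were mostly small. At least 2 fold was reached by 625 risen and 762 fallen genes and at least 4 fold by 98 and 197, and the median absolute log2 fold change of all tested genes was 0.42. The estimated biological coefficient of variation was 0.0171, so the test takes nearly every difference beyond counting noise as a change. In a likelihood ratio test with an assumed coefficient of 0.2, 639 genes were higher and 767 lower, and named genes with log2 fold changes of up to 1.06 in size were among the calls lost.

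**Figure D1:**
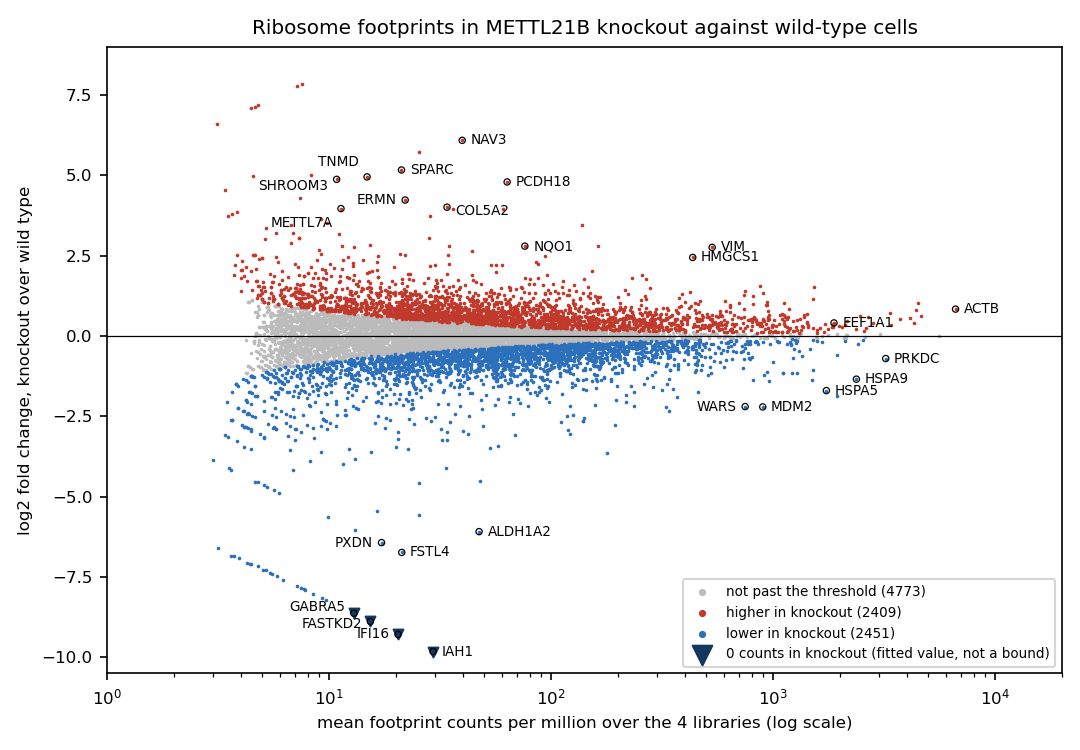
Log2 fold change of each tested gene, knockout over wild type, against its mean footprint CPM over the 4 libraries on a log scale. Red points are the 2409 genes higher and blue points the 2451 genes lower in the knockout (edgeR adjusted p under 0.05), grey points the rest, circles are genes named in the text and triangles are named genes with 0 counts in the knockout, whose fitted value is not a bound.

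The 8 largest rises were genes almost silent in the wild-type libraries. NAV3, a neuron navigator that binds microtubule ends, went from 5 counts over the wild-type libraries to 239 over the knockout libraries (1.04 ± 0.800 against 78.5 ± 3.80 CPM, n = 2 per group; log2 fold change 6.09, SE 0.31, edgeR adjusted p = 2.16e-19). PCDH18, a protocadherin, rose from 4.33 ± 0.113 to 122 ± 3.72 CPM (4.80). The matrix genes SPARC and COL5A2 rose by log2 fold changes of 5.17 and 4.01, TNMD by 4.96, ERMN by 4.24 and METTL7A by 3.97. SHROOM3, which binds actin in epithelia, had 3 counts in wild type and 64 in knockout, a ratio of 32.3 (95% exact binomial interval 10.6 to 161).

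The largest falls included genes with no knockout counts at all. IAH1 had 272 counts over the wild-type libraries and 0 over the knockout libraries, at least 59.9-fold lower. The DNA sensor IFI16 was at least 41.4-fold lower, FASTKD2, a mitochondrial RNA-binding protein, at least 31.3-fold and the receptor subunit GABRA5 at least 26.2-fold. FSTL4 had 193 counts against 1, a ratio of 127 (interval 22.6 to 5061), and PXDN, a peroxidase of the basement membrane, 156 against 1, a ratio of 103 (interval 18.2 to 4096). ALDH1A2, which makes retinoic acid, fell from 93.4 ± 4.55 to 1.30 ± 0.904 CPM (log2 fold change -6.09, SE 0.31, edgeR adjusted p = 1.89e-19).

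The most abundant genes moved by smaller folds. ACTB rose from 4753 ± 62.7 to 8508 ± 160 CPM (log2 fold change 0.84, edgeR adjusted p = 1.54e-26), followed by HSP90AA1 (0.82), ACTG1 (0.64), HSPA8 (0.58) and EEF2 (0.40). HSPA9, the mitochondrial HSP70, fell from 3399 ± 26.7 to 1342 ± 44.3 CPM (-1.34, edgeR adjusted p = 4.08e-30). PRKDC, the DNA-dependent protein kinase (-0.70), HNRNPU (-0.24) and TOP2A (-0.17) fell too. For CLTC, the clathrin heavy chain, the log2 fold change was -0.11 (edgeR adjusted p = 0.0029). Its call ended with upper quartile scaling (-0.07, edgeR adjusted p = 0.122) and without wild-type replicate 1 (-0.11) or knockout replicate 1 (-0.06). In the likelihood ratio test with an assumed coefficient of 0.2, CLTC, ACTG1, HSPA8, EEF2, PRKDC, HNRNPU and TOP2A were not called. CLTC, HNRNPU and TOP2A were lost already with a coefficient of 0.1. ACTB, HSP90AA1 and HSPA9 kept their calls in both.

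Of the gene lists, 15 of 34 passed the limma camera test with its preset correlation, and 0 passed with an estimated correlation. Estimated correlations of the 15 lists ran from -0.062 (NRF2 targets) to 0.086 (p53 target genes), with -0.031 for cholesterol biosynthesis. With 4 libraries that version of camera has little power, so its adjusted p-values below do not show that correlated genes made the calls. The highest median was that of cholesterol biosynthesis. Of 22 measured members, 21 rose and 1 fell, also when adjusted over the list alone, and 13 and 0 with the wider spread, with a median log2 fold change of 1.08 (list adjusted p = 1.13e-07, and adjusted p = 0.206 with an estimated correlation). HMGCS1, the enzyme that makes HMG-CoA, rose from 135 ± 1.42 to 734 ± 23.7 CPM (log2 fold change 2.45, SE 0.062, edgeR adjusted p = 1.16e-29). MSMO1, a sterol oxidase, rose by 1.71, and PMVK was the member that fell (-0.77).

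In the cytoskeleton list more genes rose than fell. Of 41 measured actin and tubulin genes and their partners, 31 rose and 6 fell, the same adjusted over the list alone (16 and 0 with the wider spread; median 0.64; list adjusted p = 7.65e-06, and adjusted p = 0.206 with an estimated correlation). VIM, an intermediate filament of mesenchymal cells, rose from 137 ± 9.37 to 925 ± 9.59 CPM (2.76, SE 0.059, edgeR adjusted p = 5.95e-32). TPM1, a tropomyosin, rose by 1.78 and the myosin light chain MYL6 by 1.37, while TMSB4X fell (-0.64).

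Cytosolic ribosomal proteins rose in 51 of 71 measured members and fell in 5, the same adjusted over the list alone, but 6 and 0 with the wider spread, with a median of 0.30 (list adjusted p = 7.65e-06, and adjusted p = 0.206 with an estimated correlation). RPL7A rose by 1.51, RPL23A by 1.03, RPLP1 by 1.03 and RPL29 by 0.96, and RPL36 (-0.49) and RPL32 (-0.40) fell. These genes have many pseudogenes, so single values are uncertain. Mitochondrial ribosomal proteins had no common direction, with 23 of 73 up and 17 down (25 and 17 adjusted over the list alone, 2 and 2 with the wider spread; list adjusted p = 0.758); MRPL16 rose (0.92) and MRPL9 fell (-1.43). Ribosome biogenesis factors had 16 of 41 up and 9 down (17 and 9 adjusted over the list alone, 3 and 0 with the wider spread; list adjusted p = 0.202 with limma camera and 0.0109 with limma fry), among them POLR1B up (1.20) and DKC1 down (-0.52).

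Genes of the cell cycle were more often higher than lower. Of 39 measured genes of DNA replication and S phase, 23 rose and 5 fell, also adjusted over the list alone (7 and 1 with the wider spread; median 0.40; list adjusted p = 0.000494, and adjusted p = 0.206 with an estimated correlation). RFC3, a subunit of the clamp loader, rose by 1.35, RRM2, a subunit of ribonucleotide reductase, by 0.89 and the helicase subunit MCM6 by 0.70, whereas POLA1 fell (-0.87). Of 40 measured genes of mitosis, 24 rose and 9 fell, again also adjusted over the list alone (5 and 0 with the wider spread; median 0.25; list adjusted p = 0.0186, and adjusted p = 0.420 with an estimated correlation), with ANLN up by 1.42, the kinesins KIF20A by 1.12 and KIF23 by 0.94, and TOP2A down.

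Targets of NRF2, the regulator of the oxidative stress response, had 9 members up and 2 down of 17 measured (9 and 3 adjusted over the list alone, 3 and 1 with the wider spread; median 0.54; list adjusted p = 0.0136, and adjusted p = 0.265 with an estimated correlation). NQO1, a quinone reductase, rose from 19 ± 0.869 to 133 ± 4.91 CPM (2.80, edgeR adjusted p = 3.87e-19). The transaldolase TALDO1 rose by 0.70 and the transketolase TKT by 0.67, while HMOX1 fell (-1.11). Cytosolic heat shock proteins and chaperonins rose in 18 and fell in 5 of 26 measured members, also adjusted over the list alone (3 and 1 with the wider spread; median 0.34; list adjusted p = 0.0346, and adjusted p = 0.275 with an estimated correlation). HSPB1 rose by 1.91 and HSP90AA1 and HSPA8 as above, and HSPA9 fell. Not all members of the list are cytosolic, since it holds the mitochondrial HSPA9, HSPD1 and HSPE1 and the ER chaperone SERPINH1. That list lost its call without wild-type replicate 1 (median 0.32), knockout replicate 1 (0.36) or knockout replicate 2 (0.30). The call also ended with a filter of 1 CPM in 2 libraries (median 0.32, limma camera adjusted p = 0.0657). Its median thus changed little in these settings. Zinc finger genes of the KRAB family, a class of repressors, had 12 of 39 measured members up and 1 down (9 and 0 adjusted over the list alone, 3 and 0 with the wider spread; median 0.37; list adjusted p = 0.0174, and adjusted p = 0.265 with an estimated correlation), with ZNF33A up by 1.35 and ZNF12 by 0.65. Their call ended when counts were thinned, with a median of 0.33 (limma camera adjusted p = 0.0741).

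In 2 lists of the endoplasmic reticulum (ER), more genes fell than rose. None of 28 measured ER chaperones and genes of the unfolded protein response rose and 19 fell, also adjusted over the list alone (0 and 8 with the wider spread; median -0.63; list adjusted p = 7.65e-06, and adjusted p = 0.206 with an estimated correlation). HSPA5, the ER chaperone BiP, fell from 2655 ± 78.1 to 818 ± 21.7 CPM (log2 fold change -1.70, SE 0.037, edgeR adjusted p = 1.14e-31). SEL1L, of the ER degradation machinery (-2.06), the chaperone CANX (-1.06) and HSP90B1 (-0.60) fell, whereas CALR (-0.04) and PDIA4 (-0.05) did not pass the test. In the machinery of ER translocation, signal peptide cleavage and N-glycosylation, 26 of 33 measured members fell and 1 rose, the same adjusted over the list alone (0 and 9 with the wider spread; median -0.46; list adjusted p = 1.82e-05, and adjusted p = 0.206 with an estimated correlation). SEC61A1, the channel of the translocon (-1.20), the oligosaccharyltransferase subunits STT3A (-1.11) and RPN2 (-1.06) and the glucosidase subunit GANAB (-0.79) fell. COPI and COPII coat genes, which act after the ER, had 8 of 22 up and 7 down (8 and 8 adjusted over the list alone, 0 and 1 with the wider spread; list adjusted p = 0.989), with COPA down (-0.80) and SEC31A up (0.47).

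Among aminoacyl-tRNA synthetases and ATF4 targets, more genes fell than rose. Of 19 measured cytosolic aminoacyl-tRNA synthetases and their scaffold genes, 15 fell and 1 rose, the same adjusted over the list alone (0 and 9 with the wider spread; median -0.75; list adjusted p = 6.76e-05, and adjusted p = 0.206 with an estimated correlation). WARS, which charges tryptophan tRNA, fell from 1228 ± 1.59 to 268 ± 27.8 CPM (-2.19, SE 0.053, edgeR adjusted p = 2.59e-30), and AARS (-1.39), MARS (-1.36) and EPRS (-1.36) fell with it. Targets of ATF4 and the integrated stress response fell in 20 of 27 measured members and rose in 3 (4 up and 20 down adjusted over the list alone, 2 and 13 with the wider spread; median -0.69; list adjusted p = 8.54e-05, and adjusted p = 0.206 with an estimated correlation). PHGDH (-1.16) and PSAT1 (-1.13), enzymes of serine synthesis, the asparagine synthetase ASNS (-1.14) and the pseudokinase TRIB3 (-2.65) fell. The members that rose were ATF4 itself (1.27), CHAC1 (2.03) and STC2 (0.45).

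p53 target genes fell in 16 of 23 measured members and rose in 3 (4 up and 17 down adjusted over the list alone, 0 and 12 with the wider spread; list adjusted p = 8.54e-05, and adjusted p = 0.275 with an estimated correlation). MDM2, the ubiquitin ligase of p53, fell from 1476 ± 13.4 to 320 ± 1.85 CPM (-2.20, SE 0.047, edgeR adjusted p = 5.95e-32). The cell cycle inhibitor CDKN1A (-1.39), SESN2 (-2.16) and the death receptor TNFRSF10B (-2.16) fell, while FDXR (0.65), BAX (0.55) and CCNG1 (0.17) rose. The median was -1.25, also with 1 gene that had 0 knockout counts at its bound. TNFRSF10B and TNFRSF10C lie in the run of 115 neighbouring genes named above, and without the genes of that run and a second one the median was -0.76 with 14 of 21 members down (list adjusted p = 0.000465). Immediate early genes, which respond to growth factors and stress, fell in 16 of 22 and rose in 2 (3 up and 16 down adjusted over the list alone, 1 and 10 with the wider spread; median -1.03; list adjusted p = 0.000415, and adjusted p = 0.206 with an estimated correlation). KLF4 (-3.45), BTG2 (-2.27), FOSL1 (-2.09) and EGR3 (-4.58), which lies in the same run of neighbours, fell, while NR4A2 (1.88) and SRF (0.83) rose. SESN2 belongs to the ATF4 list too, and BTG2 to the p53 list.

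Lysosomal genes fell in 19 of 31 measured members and rose in 2, the same adjusted over the list alone (1 and 9 with the wider spread; median -0.60; list adjusted p = 0.000277, and adjusted p = 0.206 with an estimated correlation). The protease CTSB (-1.99), the ceramidase ASAH1 (-1.84), the proton pump subunit ATP6V1B2 (-0.90) and PSAP (-0.62) fell; the first 3 of these lie in the run of 115 neighbouring genes. Without the genes of both runs 16 of 28 lysosomal members fell and 2 rose (median -0.48; list adjusted p = 0.00194).

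**Figure D2:**
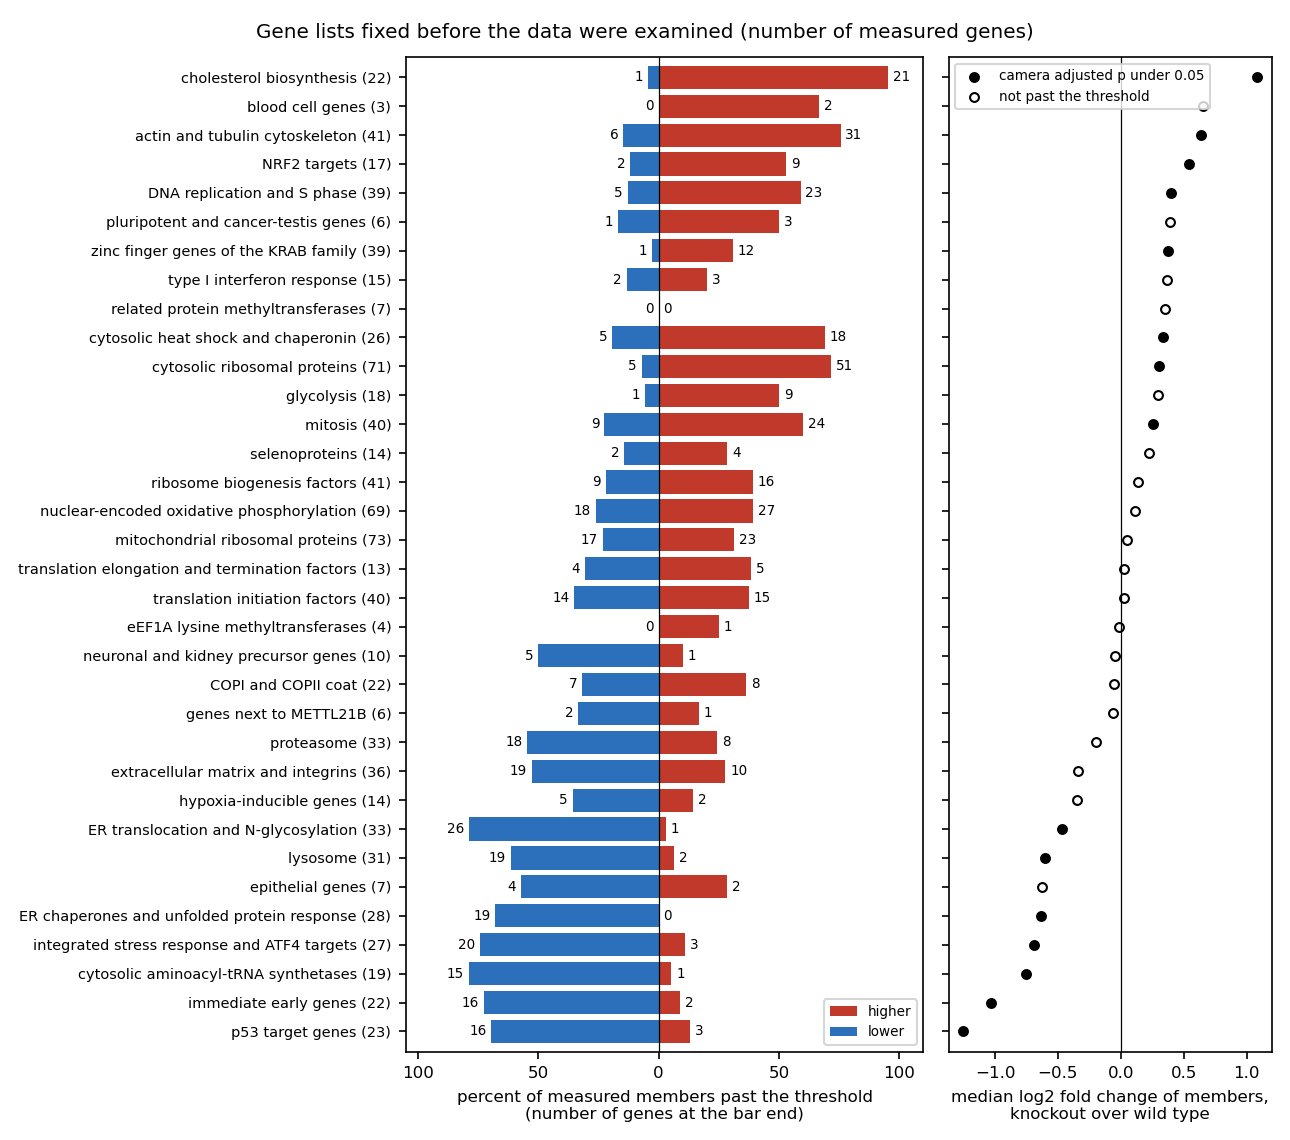
Gene lists with at least 3 measured genes (number in brackets), ordered by median. Left, percent of measured members higher (red) or lower (blue) in the knockout with edgeR adjusted p under 0.05, with the number of genes at the end of each bar; right, median log2 fold change, filled where the limma camera adjusted p with the preset correlation was under 0.05, as for cholesterol biosynthesis (1.08) and p53 target genes (-1.25).

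The remaining lists did not pass with limma camera. With limma fry, which tests a list against no change and not against the other genes, 4 of them passed: the proteasome (adjusted p = 0.000534), hypoxia-inducible genes (adjusted p = 0.028), selenoproteins (adjusted p = 0.034) and glycolysis (adjusted p = 0.0409). Glycolysis had 9 of 18 measured members up and 1 down (2 and 0 with the wider spread; list adjusted p = 0.067), with HK2 up by 1.43 and GAPDH by 0.53. Nuclear-encoded oxidative phosphorylation had 27 of 69 up and 18 down (3 and 2 with the wider spread; list adjusted p = 0.247), with COX7B up by 0.88 and ATP5A1 by 0.39. For both the counts were the same adjusted over the list alone. Of the mitochondrially encoded genes 2 were measured, too few for a list test; MT-CO1 fell (-1.56) and MT-ND4L did not pass (-0.22), with 0 up and 1 down adjusted over the list alone and with the wider spread. The proteasome had 8 of 33 up and 18 down (8 and 19 adjusted over the list alone, 0 and 1 with the wider spread; list adjusted p = 0.186), with the deubiquitinase PSMD14 (-1.06) and the ATPase PSMC3 (-0.78) down. Hypoxia-inducible genes had 2 of 14 up and 5 down, also adjusted over the list alone (1 and 2 with the wider spread; list adjusted p = 0.202), with P4HA2 (-2.47) and PDK1 (-1.06) down and SLC2A1 up (0.86). Of 36 measured genes of the extracellular matrix and integrins, 10 rose and 19 fell, the same adjusted over the list alone (7 and 13 with the wider spread; list adjusted p = 0.202). Their members moved far apart: the collagen IV chains COL4A5 and COL4A6 each rose by 3.94 and FBN2 fell (-1.07). Type I interferon genes had 3 of 15 up and 2 down, also adjusted over the list alone (1 and 0 with the wider spread; list adjusted p = 0.545), with HERC5 down (-0.85), and selenoproteins 4 of 14 up and 2 down, again also adjusted over the list alone (2 and 0 with the wider spread; list adjusted p = 0.270), with SEPW1 up by 1.33 and MSRB1 by 1.55.

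Lists that mark cell types did not pass with limma camera either, and with limma fry the pluripotency and cancer-testis list alone passed (adjusted p = 0.00319). These tests compare the groups, so they do not bear on which cell line was used. Of 23 neuronal and kidney precursor genes among the deposited genes 10 were measured, and NEFH and NEFM had 0 counts in every library. Genes of neuronal and kidney precursors had 1 of 10 measured members up and 5 down (2 and 5 adjusted over the list alone, 1 and 2 with the wider spread; list adjusted p = 0.767); TUBB3 rose (1.61) and UCHL1 fell (-0.33). Blood cell genes had 21 members among the deposited genes, of which 3 were measured. PTPRC, SPI1 and GATA1 were among the members of this list with 0 counts in every library. MYB rose by 1.67 and GATA2 by 0.65 and 0 fell, also adjusted over the list alone (1 and 0 with the wider spread, camera list adjusted p = 0.317). The call of GATA2 was lost without wild-type replicate 1 (0.60) or knockout replicate 2 (0.38). It was also lost after thinning (0.65, edgeR adjusted p = 0.0777) and with DESeq2 (0.64, adjusted p = 0.208). Pluripotency and cancer-testis genes had 3 of 6 up and 1 down, also adjusted over the list alone (1 and 1 with the wider spread; median 0.39, also with a gene at 0 at its bound; list adjusted p = 0.203). LIN28A had 0 counts in wild type and 19 in knockout, at least 9.59-fold higher, and UTF1 fell (-1.21); with DESeq2 its log2 fold change was -1.22 and the call was lost (adjusted p = 0.065). Epithelial genes had 2 of 7 up and 4 down (2 and 5 adjusted over the list alone, 1 and 3 with the wider spread; list adjusted p = 0.270), with KRT8 up by 2.22 and its partner KRT18 down (-0.92), and the desmosomal gene DSP down (-0.63). No replication-dependent histone was found under the symbols of its list, and the single long noncoding RNA found had 0 counts, so 0 members of either list were measured.

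**Figure D3:**
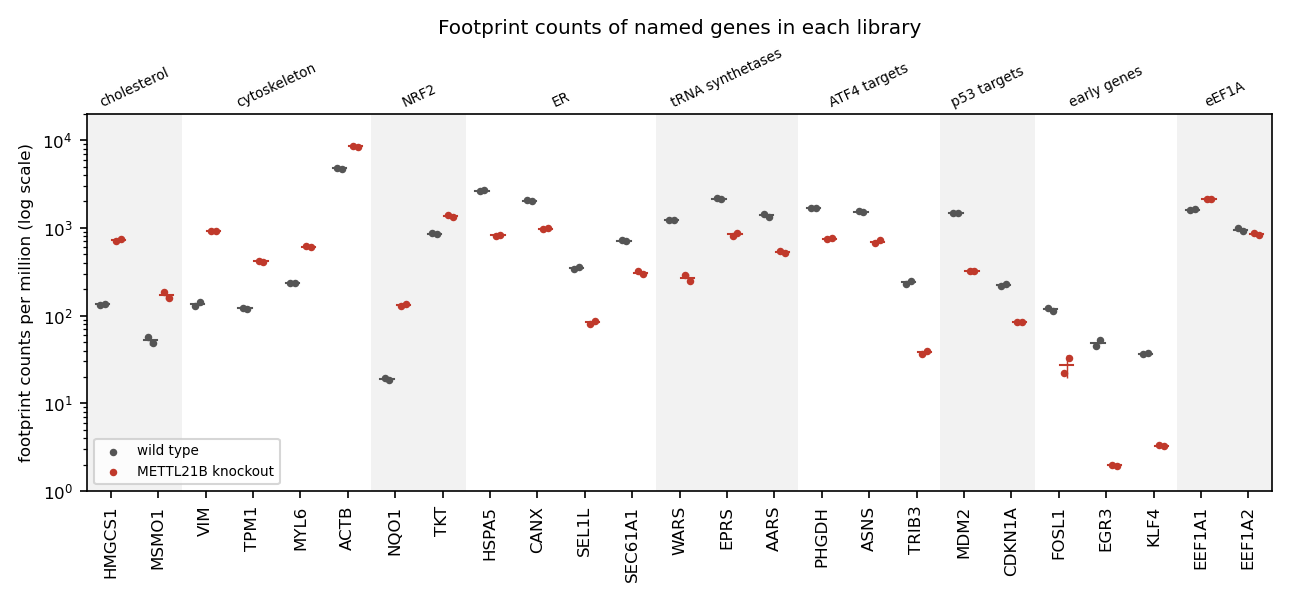
Footprint CPM (log scale) of genes from the lists in each library, with wild type in grey and METTL21B knockout in red; points are the 2 libraries of a group, lines their mean and bars the SD. The groups do not overlap for any gene shown, as for VIM (137 and 925 CPM on average) and HSPA5 (2655 and 818 CPM).

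These directions describe ribosome footprints, and a change in RNA level was not separated from a change in ribosome loading. With 2 libraries per group of unknown independence, adjusted p-values of single genes speak of the spread between these libraries alone. Those of lists from camera with its preset correlation take genes, not libraries, as replicates, so they do not measure that spread.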

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

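Chosen after the data were seen were the fits with an assumed coefficient of variation, the test against a fold of 1.5, and the fits without rows that lack a symbol or without the 2 blocks of neighbouring genes. DESeq2 called 1286 genes higher and 1393 lower, all of them among edgeR's 2409 and 2451; the cause was not tested. With an assumed coefficient of 0.2 and a likelihood ratio test in place of the quasi-likelihood test, 639 and 767 genes were called, and the effects of these 2 changes were not separated. Against a fold of 1.5, 613 and 753 were called, since that test asks for more than a difference from 0. Leaving out 1 library at a time gave 1912 to 2117 higher and 2051 to 2116 lower genes; the lone library of a group is then assumed to vary like the other group. Other scalings, limma-voom, other filters, thinning and the remaining fits gave 1744 to 2606 higher and 1807 to 2615 lower genes. No scaling moved the median log2 fold change of all genes by more than 0.043. With the replicate number as a block, 2432 and 2477 genes were called; deviations of libraries with the same number had a correlation of 0.0007 across genes, so the number was not taken as pairing libraries, and no call of a list or named gene changed under it. The log2 fold change of METTL21B ran from -1.34 to 0.18 with 1 library left out and passed under no setting.

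The 15 lists became 0 with an estimated correlation and 14 or 15 under other settings of camera. The list raised in the simulation was also lost with an estimated correlation, so that loss cannot tell a changed list from an unchanged one. Fry, which tests a list against no change, called 22, including the 15; translation initiation factors passed there as a fall although their median was 0.021 (adjusted p = 0.0429). Of 154 genes picked by the naming rule 53 changed their call under some setting, 50 of them with an assumed coefficient of 0.2 and 9 with DESeq2. In the simulation, where few genes changed, 26% of the smallest changes were found. That share does not carry over to these data, but a gene that did not pass is still not shown to be unchanged.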

Other observations

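The test of knockout depth on the nearly absent genes was chosen only after the result it bears on was seen. Genes read in wild type and nearly absent in the knockout went beyond those named by rule. With at least 50 counts over the wild-type libraries and at most 3 over the knockout libraries there were 26 genes with a symbol. Besides those above they held EGFR, the epidermal growth factor receptor (90 counts against 0), NR3C1, the glucocorticoid receptor (58 against 0), the DNA sensor MB21D1, also called cGAS (86 against 0), the kinase SYK (90 against 1), the ligand BMP2 (78 against 0), the adhesion molecule VCAM1 (53 against 0) and the DNA repair enzyme MGMT (231 against 3). These genes were chosen after their values were seen.

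The first pattern is that SHROOM3 alone met the rule the other way round, 1 gene against 26. In 20 random draws thinned to the smallest library, 13 to 17 genes were nearly absent in the knockout and 1 to 6 in wild type. Genes nearly absent in wild type made up a share of at most 0.300, so depth was part of the asymmetry but not the whole of it. Loss of expression in a knockout clone, by silencing or deletion, and RNA of other cells in the wild-type libraries were not tested, so both stay open.

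A second pattern is that changes ran along the genome. Over windows of 30 consecutive tested genes, 9182 of which could be placed, the largest absolute median log2 fold change was 1.10, against a highest value of 0.762 in 1000 shuffles of gene order, and 19 of 1713 windows passed every shuffle. These windows formed 2 blocks. From ERICH1 to CEBPD, 115 genes had a median of -0.83 (quartiles -1.24 and -0.51), 88 called lower and 2 higher with edgeR. The 25 genes after it had a median of -0.09, and too few placed genes lay before it on its chromosome for a median. From KARS to ZC3H18, 35 genes had a median of 0.68, 21 called higher and 4 lower. The 25 genes before it had a median of 0.01 and the 25 after it 0.59, so its end is not sharp. Its start was set by whole windows. KARS (-0.89), TERF2IP (-0.28) and MAF (-2.90) were called lower, and CMC2 (1.27) was the first gene called higher. A difference in DNA copy number between the cells of the groups is a candidate explanation. Windows within the range of the shuffles would have argued only against differences over 30 or more genes with a median beyond 0.762 in size. Shorter or smaller differences would have gone unseen, so the 2 blocks may not be all such regions. The windows cannot tell copy number from regional silencing, which was not tested, and no DNA data were analysed here. Without both blocks 2337 genes were higher and 2381 lower, so they hold few of the calls. That fit also left out the lowered genes at the start of the second block and kept the 25 genes after its end.

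The third pattern is the number of genes called, 4860 in all. After thinning to the smallest library a share of 0.832 was still called in the same direction, which argues against depth as the whole cause. The scalings tried differed too little from each other to test scaling as a cause. How many genes replicates from separate cultures would call was not tested. The effect of the genotype and differences between clones or cultures that have nothing to do with METTL21B were not told apart by this design and stay open.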
